A study of activated sludge metagenome with 9 samples.

How the data were processed

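The series holds 9 libraries of DNA from mixed microbial cultures in 3 groups of 3 named LS, SS and SS-NS in the sample titles, which also give the replicate numbers. Per the labels' protocols, DNA was extracted with the DNeasy PowerSoil kit and full-length 16S rRNA gene amplicons were prepared with the SMRTbell Prep Kit 3.0 for PacBio sequencing. The deposited table gives the authors' read counts per sequence variant and library, as whole numbers that were not normalised. A second deposited table gives the lineage of each variant from kingdom to species with the classifier's confidence as a fraction, 0.95 or higher for every variant. The denoiser, the filters, the classifier and the reference taxonomy were not given in the sources used here. Genus names of the form midas_g_11604 stand in the table as placeholders for groups without a formal name, and 47 of the 163 genus-level units carry one. A variant is known here by its identifier and lineage only, since its sequence was not used here.

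The table held 515 variants and 90605 reads, between 8667 and 11451 per library. No count equalled 1, so lower counts may have been removed before deposit, and a 0 is described as no reads listed, with no upper limit and no fold against it. Of the variants, 280 were listed in 1 library, with 2.22% of all reads, and 7 in every library. Reads were summed per genus, and the 16 variants without a genus name (0.188% of reads) were summed at their lowest named rank. Reads of PCR products without molecular identifiers are not independent molecules. Shares of reads are not shares of cells, because 16S copies per genome and extraction differ between genera. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom between 2.44 and 35.5 over genera), so none was treated as a repeat deposit of 1 library. Repeated extractions or PCRs of 1 culture could differ as much and are not excluded. Sample names share a stem between SS and SS-NS at each replicate number, so those libraries may be linked. Deviations of same-number SS and SS-NS libraries correlated at 0.078, 0.033 and 0.070 for replicates 1, 2 and 3, while those with LS took both signs. With 3 libraries per group, such values cannot decide on pairing. The planned tests treated the libraries as unpaired.

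Before the data were examined, the groups, tests, alternatives, 10 genus lists and the rule for naming genera were fixed. Genus-level units with at least 10 reads in at least 3 of the 9 libraries, 69 in all, were tested on the deposited counts with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, all 9 libraries in 1 fit, two-sided contrasts) in R 4.3.3. Calls had a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the fold change and its F statistic. TMM factors ranged from 0.595 to 1.74 and moved fold changes against ratios of shares by −0.87, −0.27 and −1.15 on the log2 scale in SS against LS, SS-NS against SS and SS-NS against LS. They also differed within SS-NS, at 1.63, 0.943 and 1.74 for replicates 1, 2 and 3. The spread within SS-NS in the planned test therefore partly reflects the scaling. Calls were therefore also counted with library totals alone, with DESeq2 size factors in edgeR, with DESeq2 1.42.0 (poscounts) and with limma 3.58.1 on centred log-ratios after adding 0.5, which with TMM make the 5 scalings. On simulated counts for 69 genera in SS against LS (20 draws), the edgeR procedure recovered 100% of genera changed 4-fold and 92.5% of those changed 2-fold, and called 0.67% of unchanged ones, at a dispersion of 0.02 for every genus. With the dispersion fitted to each genus in the real counts (median 0.0973), it recovered 71.2% and 22.5% and called 0.195%, so a genus that did not pass may still have changed. The simulated changes fell on a few genera with enough reads, equally up and down, from shares averaged over all libraries. They held no large shift of the whole community, so the simulation gives no error rate for calls that depend on scaling.

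Bray-Curtis dissimilarity of variant shares was compared with PERMANOVA. The Shannon index and the number of variants were averaged over 100 rarefactions to 8667 reads. These values and the list shares were tested by exact permutation of the F statistic over all 280 partitions of the 9 libraries, for which 0.00357 is the smallest p. List shares were adjusted over the 7 lists with reads. The lists were PHA-storing, filamentous, polyphosphate-accumulating, glycogen-accumulating, nitrifying, predatory, flanking Bacteroidota, sewage and gut, and anaerobic fermenting or sulfate-reducing genera, and organelles. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

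The genera named were the 10 with the highest mean share, then, per comparison, up to 6 in each direction with the largest absolute log2 fold change among called genera at 0.5% of reads or more in a group and without overlap between libraries, then every list member at 0.5% or more in a group. The 5 variants with the highest mean share were also named. Azonexus, Simplicispira, Nannocystis and Lentimicrobium fall outside this rule and were named, after their values were seen, as members behind a list's count. Lactobacillus, Ligilactobacillus, Bacteroides and Verrucomicrobium, given under other observations, also fall outside it and were not planned. Alternatives covered the scaling, the filter on low counts (none, or 50 reads), taxa without a genus name, variants or families in place of genera, the replicate number as a block, each library left out in turn and the libraries in the fit. For whole communities they covered the distance, rank, scale and filter, and for the PHA-storing and filamentous shares the denominator, the log scale and the most abundant member. Alternatives chosen after seeing the data were variants outside Sphaerotilus, Sphaerotilus on the PHA-storing list, the most abundant member left out of 4 other lists, totals without Sphaerotilus or without Sphaerotilus and Neomegalonema, and a repeated filter in fits with fewer libraries. Fits on totals without these genera used no TMM factors.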

Results

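Full-length 16S rRNA gene amplicons were sequenced on the PacBio platform from 9 libraries of mixed microbial cultures selected for polyhydroxyalkanoates (PHA), which are carbon reserve polymers that bacteria store inside the cell. The libraries fell into 3 groups of 3, labelled LS, SS and SS-NS, which stand for 3 ways of operating the culture. The series concerns short settling combined with aerobic dynamic feeding, in which aerated sludge receives its substrate in pulses, and asks how this affects selection of the culture and its resilience to bulking, the poor settling of sludge rich in filaments. The labels do not spell out the abbreviations. Each library held between 8667 and 11451 reads, 90605 in all, divided among 515 sequence variants and 163 genus-level units. Below, values are the mean share of a library's reads ± SD with n = 3 libraries per group. No label says whether the 3 replicates of a group were separate cultures, so every p-value measures the spread between these samples, which may be technical.

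The 3 communities were dominated by different genera. In LS, Leadbetterella of the Bacteroidota (27.2% ± 2.31), the rhodobacteracean placeholder genus midas_g_11604 (26.1% ± 2.20) and the sheathed filamentous bacterium Sphaerotilus (19.5% ± 1.5) held most reads. In SS, Neomegalonema (18.4% ± 1.61), a filamentous alphaproteobacterium known to store PHA, and Sphaerotilus (17.1% ± 2.14) led, followed by Flavobacterium (8.67% ± 0.752). In SS-NS, Sphaerotilus alone held 56.9% ± 6.15 of reads and Neomegalonema 23.0% ± 2.31. The groups were distinct as whole communities: group membership took up 96.5% of the variation in Bray-Curtis dissimilarity between variant profiles (pseudo-F = 81.8, exact permutation p = 0.00357, the smallest that 280 partitions allow). Mean dissimilarity within groups lay between 0.103 and 0.171, against 0.711 between LS and SS, 0.614 between SS and SS-NS and 0.856 between LS and SS-NS. Of 69 genus-level units with enough reads to test, 61 differed among the 3 groups by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

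**Figure D1:**
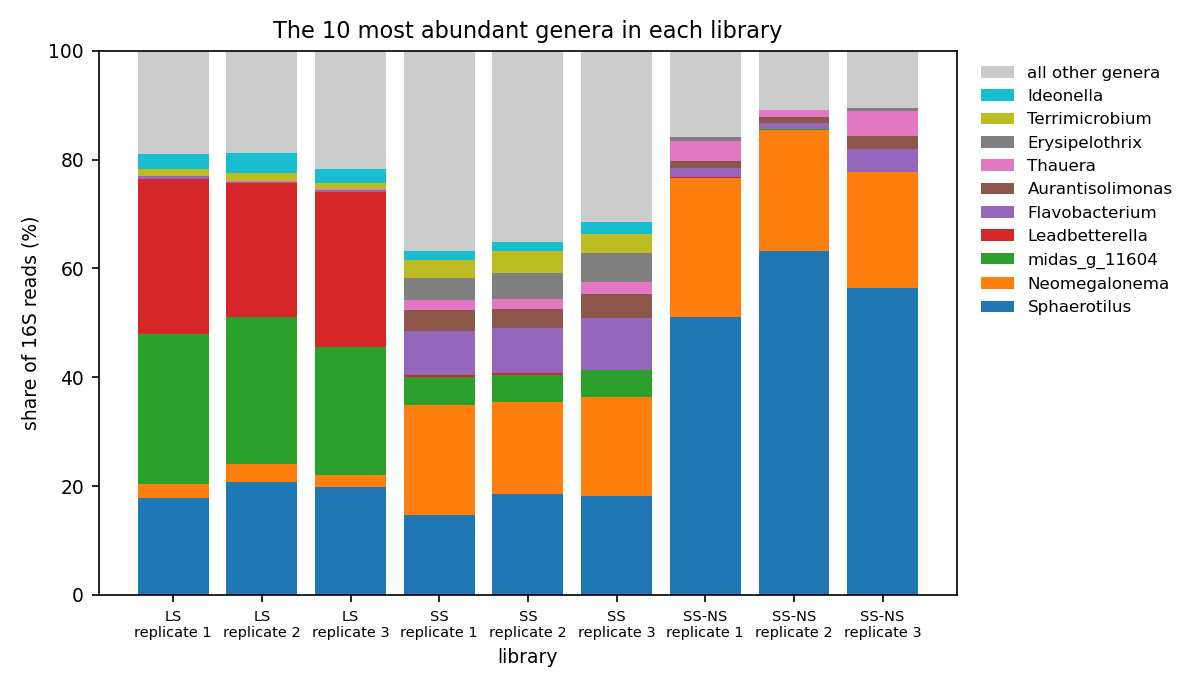
Share of 16S reads (%, vertical axis) of the 10 genera with the highest mean share in each of the 9 libraries (horizontal axis), stacked, with all other genera in grey. Leadbetterella and midas_g_11604 make up most of the LS bars, and Sphaerotilus reaches 56.9% on average in SS-NS.

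The first comparison set SS against LS. Leadbetterella fell from 27.2% ± 2.31 of reads in LS to 0.206% ± 0.191 in SS, a share 132 times lower (log2 fold change −7.93, SE 0.95, edgeR adjusted p = 0.000158). One SS library had no Leadbetterella reads listed, and the SS mean was 0.12% without SS replicate 1. Neomegalonema rose 7.0 times, from 2.63% ± 0.535 to 18.4% ± 1.61 (log2 fold change 1.94, SE 0.31, edgeR adjusted p = 0.000565), and Flavobacterium, whose members degrade polymers in many water habitats, rose 23.5 times, from 0.369% ± 0.0458 to 8.67% ± 0.752 (edgeR adjusted p = 7.54e-05). The PHA-storing genus Thauera rose 17.0 times, from 0.115% ± 0.0312 to 1.96% ± 0.105 (edgeR adjusted p = 5.53e-05). Midas_g_11604 fell from 26.1% ± 2.20 to 5.11% ± 0.0854 (log2 fold change −3.23, SE 0.97, edgeR adjusted p = 0.0156), a call that held under 2 of 5 scalings of the counts and missed the threshold without LS replicate 1, SS replicate 1 or SS replicate 2 at a similar fold change (−3.20 to −3.14 on the log2 scale). The multiples in this paragraph are ratios of shares, while the tested fold changes lie 0.87 log2 units lower through the TMM factors. The fall of Leadbetterella and midas_g_11604 by itself raises the shares of all other genera in SS.

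Several genera had reads in one of these groups and none listed in the other. Erysipelothrix, a genus of Firmicutes, reached 4.69% ± 0.726 in SS with no reads listed in any LS library. The same held for Aurantisolimonas (3.90% ± 0.501), midas_g_65547 (3.59% ± 0.246), Wandonia (1.94% ± 0.376), midas_g_89500 of the Verrucomicrobiota (1.42% ± 0.410), midas_g_81585 of the Chloroflexi (0.993% ± 0.227) and Paracoccus (0.947% ± 0.102). In the opposite direction, Pseudomonas (0.823% ± 0.186), Rhodobacter (0.556% ± 0.0987) and midas_g_155 (0.529% ± 0.116) were listed in LS and had no reads in SS. Dyadobacter fell from 0.507% ± 0.184 to 0.0134% ± 0.0232 and midas_g_896 from 0.695% ± 0.0449 to 0.0436% ± 0.0408, the former with reads in SS replicate 2 alone and the latter at 0.0251% without SS replicate 3. All 12 of these calls held under each of the 5 scalings, with edgeR adjusted p between 5.12e-05 and 0.00237. No fold is given against a group without reads, because no listed count was below 2.

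Among genera at more moderate shares, Arenimonas rose from 0.235% ± 0.0149 to 2.97% ± 0.205, Ferruginibacter from 0.0651% ± 0.0265 to 1.81% ± 0.228 and Terrimicrobium from 1.29% ± 0.0737 to 3.66% ± 0.435, the last a call lost without LS replicate 2 or 3 or SS replicate 2 (0.50 to 0.64 on the log2 scale, against 0.64 with all libraries) and with no filter on low counts (0.62). Devosia fell from 1.48% ± 0.594 to 0.287% ± 0.0875, midas_g_51 from 0.966% ± 0.0996 to 0.383% ± 0.168 and Ideonella from 3.01% ± 0.721 to 1.77% ± 0.314. Sphaerotilus passed the test as lower in SS (log2 fold change −1.05, SE 0.39, edgeR adjusted p = 0.0375), but its shares of 19.5% ± 1.5 and 17.1% ± 2.14 overlapped between libraries and the call held under only 2 of 5 scalings and missed the threshold without LS replicate 1 or 2 or SS replicate 1 or 2 at −1.09 to −0.92. Emticicia, at 1.48% ± 0.202 and 1.49% ± 0.192, was also called lower, but the call held under 2 of 5 scalings, its direction flipped with library totals alone, and it was lost without LS replicate 3 (−0.92 on the log2 scale). Acidovorax (1.24% ± 0.109 and 1.88% ± 0.126), Brevundimonas (1.20% ± 0.158 and 2.22% ± 0.403) and Hydrogenophaga (1.10% ± 0.0860 and 2.68% ± 0.472) did not pass, although their shares did not overlap and 3, 2 and 4 of the 5 scalings called them higher. Over the 4 scalings other than the planned one, log2 fold changes were 0.07 to 0.60 for Acidovorax, against −0.28 as planned, 0.35 to 0.88 for Brevundimonas and 0.75 to 1.29 for Hydrogenophaga.

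Of the 13 tested members of the PHA-storing list, 4 rose in SS (Azoarcus, Neomegalonema, Paracoccus and Thauera), 4 were called lower (Azonexus, Comamonas, Pseudomonas and Rhodobacter) and 5 did not pass, with the same counts when adjusted over the list alone. The call of Comamonas, at 0.551% ± 0.0312 and 0.504% ± 0.103, was made under 1 of 5 scalings and lost without LS replicate 3 (−1.02 on the log2 scale). Both filamentous genera with reads passed, Neomegalonema as higher and Sphaerotilus as lower, and both did so adjusted over the list alone. Of 6 tested genera on the list of flanking Bacteroidota, which hydrolyse polymers around flocs, Flavobacterium and Ferruginibacter rose, Leadbetterella and Dyadobacter fell, Emticicia was called lower at near equal shares, and 1 did not pass, again the same adjusted over the list alone.

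In total, 48 of 69 units differed between SS and LS, 22 higher and 26 lower in SS (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 69, 55 showed no overlap between the groups' libraries, where chance gives 10% of units. All 22 higher calls and 22 of the 26 lower calls were made under each of 5 scalings. TMM factors placed fold changes 0.87 log2 units below the ratio of shares in this comparison, so a genus at equal shares counts as lower, and the split moved to 31 higher and 22 lower with DESeq2, 29 and 22 with its size factors in edgeR.

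The second comparison set SS-NS against SS. Sphaerotilus rose from 17.1% ± 2.14 to 56.9% ± 6.15 of reads, 3.32 times (log2 fold change 1.54, SE 0.39, edgeR adjusted p = 0.00898), a call lost with a minimum of 50 reads, where the log2 fold change was 0.23. Arcobacter, a genus common in sewage, rose from 0.0341% ± 0.0296 to 2.68% ± 1.73 (1.69% without SS-NS replicate 1), and Pseudomonas (2.50% ± 1.37) and the floc-forming Zoogloea (1.03% ± 0.262) appeared in SS-NS with no reads listed in SS. These 4 genera were all that passed as higher, and each was called under the 5 scalings. Neomegalonema, at 18.4% ± 1.61 and 23.0% ± 2.31, had libraries that did not overlap but did not pass the planned test (log2 fold change 0.09, SE 0.29, edgeR adjusted p = 0.970). Of the 5 scalings 3 called it higher, the 4 others than the planned one giving 0.32 to 2.90 with adjusted p between 3.83e-06 and 0.204 in edgeR, DESeq2 or limma. With a minimum of 50 reads it was called lower at −1.17, although its share was higher. That filter also recomputed the TMM factors. It lowered Sphaerotilus (1.54 to 0.23) and Neomegalonema (0.09 to −1.17) by similar amounts, so the sign of −1.17 depends on the scaling. Thauera, at 1.96% ± 0.105 and 3.19% ± 1.70, did not pass the planned test either (edgeR adjusted p = 0.412). It too was called higher under 3 of 5 scalings, with 0.71 to 3.10 and adjusted p between 1.14e-05 and 0.189 in edgeR, DESeq2 or limma, and gave −0.77 with a minimum of 50 reads.

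Losses were broader. Of 37 units called lower in SS-NS, 21 had no reads listed there. They included Terrimicrobium (3.66% ± 0.435 in SS), midas_g_65547 (3.59% ± 0.246), Arenimonas (2.97% ± 0.205), Acidovorax (1.88% ± 0.126), Ferruginibacter (1.81% ± 0.228), Ideonella (1.77% ± 0.314) and Emticicia (1.49% ± 0.192), with edgeR adjusted p between 6.92e-07 and 2.68e-05. Among genera with reads left in SS-NS, midas_g_11604 fell from 5.11% ± 0.0854 to 0.0674% ± 0.117, with reads in SS-NS replicate 2 alone, Hydrogenophaga from 2.68% ± 0.472 to 0.148% ± 0.0299, Erysipelothrix from 4.69% ± 0.726 to 0.522% ± 0.312 and Brevundimonas from 2.22% ± 0.403 to 0.251% ± 0.151 (0.166% without SS-NS replicate 1). The calls of Erysipelothrix and Brevundimonas held under 4 of 5 scalings and not on centred log-ratios, where log2 fold changes were −0.81 and −0.69. Without SS-NS replicate 3, the SS-NS mean was 1.26% for Flavobacterium and 0.696% for Wandonia. Flavobacterium (8.67% ± 0.752 to 2.21% ± 1.68), Aurantisolimonas (3.90% ± 0.501 to 1.59% ± 0.703), Wandonia (1.94% ± 0.376 to 1.12% ± 0.741), Paracoccus (0.947% ± 0.102 to 0.515% ± 0.160), Azoarcus (0.713% ± 0.311 to 0.220% ± 0.133) and Comamonas (0.504% ± 0.103 to 0.105% ± 0.0360) also passed as lower, but Comamonas did so under 4 of 5 scalings, Flavobacterium and Aurantisolimonas under 2, and Wandonia, Paracoccus and Azoarcus under the planned one alone. The direction of all 6 flipped on centred log-ratios, where Aurantisolimonas, Wandonia and Paracoccus were called higher, and that of Wandonia and Paracoccus also with DESeq2. Wandonia was no longer called without LS replicate 3, SS replicate 1 or 3 or SS-NS replicate 1 or 2 (−1.39 to −0.96 on the log2 scale), nor Azoarcus without SS replicate 1 or 2 or SS-NS replicate 2 or 3 (−2.06 to −1.77). Leadbetterella, at 0.206% ± 0.191 and 0.158% ± 0.0325, did not pass (edgeR adjusted p = 0.617), but was called higher on centred log-ratios (3.56) and lower without SS replicate 3 (−1.19).

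Of the 13 tested PHA-storing genera, Pseudomonas and Zoogloea rose, 7 were called lower and 4 did not pass, the same when adjusted over the list alone. The 7 were Acidovorax, Azoarcus, Brevundimonas, Comamonas, Hydrogenophaga, Paracoccus and Simplicispira, of which 3 were called lower under each of the 5 scalings. On the filamentous list Sphaerotilus rose under each of the 5 scalings, and Neomegalonema was called higher under 3 of them but not the planned one. On the flanking Bacteroidota list, Emticicia, Ferruginibacter and Flavobacterium were called lower, the first 2 under each of the 5 scalings, none was called higher and 3 did not pass. Arcobacter was the single member of 3 tested on the sewage and gut list that rose.

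Altogether 41 of 69 units differed, 4 higher and 37 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 39 of the 69 showed no overlap between libraries (10% by chance). This split depended on scaling: centred log-ratios in limma gave 27 higher and 22 lower, and the 5 scalings shared 4 higher and 22 lower calls. The 27 include genera with no reads listed in either group, such as Rhodobacter and midas_g_155, whose sign comes from the added count alone. Both gave 2.45 on the log2 scale there, so that scaling moved fold changes in this comparison upward.

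The third comparison set SS-NS against LS. Leadbetterella fell from 27.2% ± 2.31 to 0.158% ± 0.0325, a share 172 times lower (log2 fold change −8.57, SE 0.98, edgeR adjusted p = 8.92e-05), and midas_g_11604 from 26.1% ± 2.20 to 0.0674% ± 0.117 (log2 fold change −9.56, SE 1.35, edgeR adjusted p = 0.000269), its SS-NS reads lying in SS-NS replicate 2 alone. As ratios of shares, Neomegalonema rose 8.73 times, from 2.63% ± 0.535 to 23.0% ± 2.31 (edgeR adjusted p = 0.000345), and Thauera 27.7 times, from 0.115% ± 0.0312 to 3.19% ± 1.70 (edgeR adjusted p = 1.69e-05). Sphaerotilus had shares of 19.5% ± 1.5 and 56.9% ± 6.15 that did not overlap, yet it did not pass the planned test (log2 fold change 0.49, SE 0.39, edgeR adjusted p = 0.284). The other 4 scalings called it higher, with adjusted p between 1.33e-12 and 0.000915 in edgeR, DESeq2 or limma, while its fold change with a minimum of 50 reads was −0.21 on the log2 scale. TMM factors differed between SS-NS replicates 1, 2 and 3 (1.63, 0.943 and 1.74), so the spread in the planned test partly reflects the scaling.

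Flavobacterium rose from 0.369% ± 0.0458 to 2.21% ± 1.68 and Azoarcus from 0.00946% ± 0.0164 to 0.220% ± 0.133. Flavobacterium averaged 1.26% in SS-NS without SS-NS replicate 3, and Azoarcus had LS reads in LS replicate 3 alone. As in SS-NS against SS, the SS-NS means of Arcobacter and Brevundimonas were 1.69% and 0.166% without SS-NS replicate 1, and that of Wandonia 0.696% without SS-NS replicate 3. The call of Flavobacterium was lost without LS replicate 3 (1.13 on the log2 scale), with a minimum of 50 reads (0.84) and with only the groups compared (1.14), and that of Azoarcus with only the groups compared (3.07). Arcobacter (2.68% ± 1.73), Aurantisolimonas (1.59% ± 0.703), Wandonia (1.12% ± 0.741), Zoogloea (1.03% ± 0.262), Erysipelothrix (0.522% ± 0.312) and Paracoccus (0.515% ± 0.160) were found in SS-NS with no reads listed in LS. Pseudomonas, at 0.823% ± 0.186 in LS and 2.50% ± 1.37 in SS-NS, overlapped between libraries and did not pass the planned test (log2 fold change 0.66, edgeR adjusted p = 0.405). The other 4 scalings called it higher, with 1.60 to 3.48 and adjusted p between 0.000174 and 0.0217 in edgeR, DESeq2 or limma, while it gave −0.14 with a minimum of 50 reads and −0.21 without SS-NS replicate 2. Ideonella (3.01% ± 0.721 in LS), Emticicia (1.48% ± 0.202), Devosia (1.48% ± 0.594), Terrimicrobium (1.29% ± 0.0737), Acidovorax (1.24% ± 0.109), midas_g_51 (0.966% ± 0.0996), midas_g_896 (0.695% ± 0.0449), Rhodobacter (0.556% ± 0.0987), midas_g_155 (0.529% ± 0.116) and Dyadobacter (0.507% ± 0.184) were listed in LS and had no reads in SS-NS. Hydrogenophaga fell from 1.10% ± 0.0860 to 0.148% ± 0.0299 and Brevundimonas from 1.20% ± 0.158 to 0.251% ± 0.151, the latter called under 4 of 5 scalings.

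Of the 13 tested PHA-storing genera, 5 rose (Azoarcus, Neomegalonema, Paracoccus, Thauera and Zoogloea), 7 were called lower, 5 of them under each of the 5 scalings, and Pseudomonas did not pass under the planned scaling, the same when adjusted over the list alone. On the flanking Bacteroidota list, Flavobacterium rose, 4 genera fell and 1 did not pass, and 5 fell when adjusted over the list alone. Arcobacter rose on the sewage and gut list. In total, 50 of 69 units differed, 12 higher and 38 lower in SS-NS (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 53 of the 69 showed no overlap between libraries (10% by chance). TMM factors placed fold changes 1.15 log2 units below the ratio of shares, and the split was 23 higher and 32 lower on centred log-ratios in limma. The 23 include genera with no reads listed in LS or SS-NS, such as midas_g_65547, whose sign comes from the added count alone.

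The share of all reads in each genus list was then compared over the 3 groups. Filamentous genera held 22.1% ± 1.80 of reads in LS, 35.5% ± 0.744 in SS and 79.9% ± 4.78 in SS-NS (exact permutation p = 0.00357, adjusted p = 0.00833 over 7 lists). Only Sphaerotilus and Neomegalonema of the 27 genera listed had reads. Leadbetterella and midas_g_11604, not on this list, held 27.2% and 26.1% of LS reads. Their fall by itself raises the list's share in SS and SS-NS, and shares without them were not tested. PHA-storing genera held 8.75% ± 0.759, 29.8% ± 2.26 and 30.9% ± 3.63 (exact permutation p = 0.0214, adjusted p = 0.0300). Neomegalonema stands on both lists, and without it the PHA-storing share was 6.12% ± 0.229 in LS, 11.3% ± 0.720 in SS and 7.95% ± 1.47 in SS-NS, which reversed the order of SS and SS-NS (exact permutation p = 0.00357). Leaving out SS-NS replicate 1 also reversed that order, to 29.8% ± 2.26 and 28.8% ± 0.247, which lie within the spread. The p-values test any difference among the 3 groups, not the order of SS and SS-NS. Sphaerotilus, which also stores PHA but was not on that list, would bring the share to 28.3% ± 1.92, 46.9% ± 0.296 and 87.8% ± 3.59.

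Flanking Bacteroidota held 29.7% ± 2.77 of reads in LS, 12.3% ± 0.386 in SS and 2.38% ± 1.69 in SS-NS, and sewage and gut genera 0.147% ± 0.0750, 0.450% ± 0.0705 and 3.35% ± 1.46 (each exact permutation p = 0.00357, adjusted p = 0.00833). In a setting chosen after seeing the data, the flanking share without Leadbetterella was 2.56% ± 0.456, 12.1% ± 0.556 and 2.22% ± 1.70, highest in SS (exact permutation p = 0.0321). The sewage and gut share without Arcobacter was 0.147% ± 0.0750, 0.416% ± 0.0999 and 0.671% ± 0.463, no longer past the threshold (exact permutation p = 0.0536). Anaerobic fermenting or sulfate-reducing genera held 0.171% ± 0.0674, 0.504% ± 0.125 and 0.0932% ± 0.0889 (exact permutation p = 0.0107, adjusted p = 0.0188). Lentimicrobium, their only tested member, was called lower in SS-NS against SS under 2 of 5 scalings, and without it the list did not pass (exact permutation p = 0.636). Of the polyphosphate-accumulating list Azonexus alone had reads, at 0.301% ± 0.0568 in LS and none listed in SS or SS-NS (exact permutation p = 0.0357, the smallest possible when the other groups have no reads, adjusted p = 0.0417). Predatory genera, at 0.243% ± 0.0936, 0.142% ± 0.126 and 0.0435% ± 0.0469, did not pass among the 3 groups (exact permutation p = 0.121), although the libraries of LS and SS-NS did not overlap, while their only tested member, Nannocystis, passed as lower in SS-NS against SS, under 3 of 5 scalings, and against LS, under each. No genus of the glycogen-accumulating, nitrifying or organelle lists had reads.

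**Figure D2:**
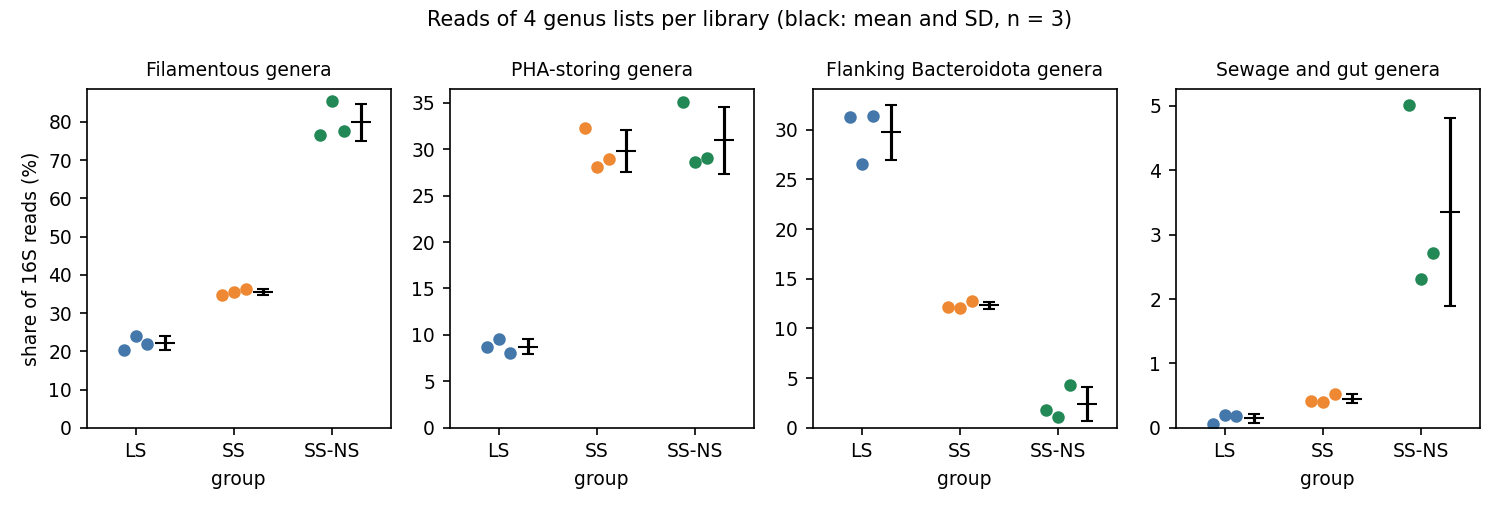
Share of 16S reads (%, vertical axes) held by 4 genus lists in each library of LS, SS and SS-NS (horizontal axes), with points for libraries and black marks for the mean and SD of 3. Filamentous genera average 22.1%, 35.5% and 79.9%, and flanking Bacteroidota 29.7%, 12.3% and 2.38%.

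Diversity within libraries also differed. The Shannon index of sequence variants (natural logarithm) was 2.88 ± 0.0482 in LS, 3.58 ± 0.0788 in SS and 2.37 ± 0.213 in SS-NS (exact permutation p = 0.00357). The number of variants at 8667 reads was 159 ± 15.6 in LS, 94.0 ± 13.2 in SS and 110 ± 12.7 in SS-NS (exact permutation p = 0.0107). Counted as genera, the order of SS and SS-NS reversed, with 81.4 ± 6.58, 61.3 ± 4.50 and 38.3 ± 2.30 (exact permutation p = 0.00357). Among genera at 0.5% of reads or more, LS had 20, SS 28 and SS-NS 12, of which LS and SS shared 11, SS and SS-NS 8, and LS and SS-NS 3. Pairs of groups have only 10 splits and cannot reach an exact p below 0.1, so no pairwise test of these values is given.

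Single sequence variants carried much of this. The 5 variants with the highest mean share were variants 1 and 2 of Sphaerotilus natans, variant 1 of Neomegalonema and the leading variants of midas_g_11604 and Leadbetterella byssophila. Sphaerotilus variant 1 held 5.50% ± 0.449 of reads in LS, 7.47% ± 1.11 in SS and 28.6% ± 3.45 in SS-NS, and variant 2 held 3.56% ± 0.213, 7.02% ± 0.995 and 24.4% ± 2.97. Neomegalonema variant 1 held 1.47% ± 0.304, 11.8% ± 1.24 and 18.8% ± 2.04. The midas_g_11604 variant held 24.6% ± 1.96, 5.06% ± 0.161 and 0.0674% ± 0.117, and the Leadbetterella byssophila variant 26.9% ± 2.07, 0.0859% ± 0.0889 and 0.0124% ± 0.0215.

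Variants of 1 genus did not keep their proportions, a comparison chosen after their values were seen. Of Sphaerotilus reads, variant 3 made up 44.5% ± 0.881 in LS, 14.2% ± 1.40 in SS and 2.20% ± 0.507 in SS-NS, while variant 1 made up 28.2% ± 0.725, 43.6% ± 1.99 and 50.3% ± 0.765 (each exact permutation p = 0.00357, adjusted p = 0.00833 over 7 variants). Of Neomegalonema reads, variant 1 made up 56.0% ± 3.79, 64.3% ± 1.11 and 81.9% ± 2.96 (exact permutation p = 0.00357, adjusted p = 0.00833) and variant 2 made up 29.5% ± 1.53, 31.8% ± 1.42 and 13.1% ± 3.05 (exact permutation p = 0.00714, adjusted p = 0.0125).

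**Figure D3:**
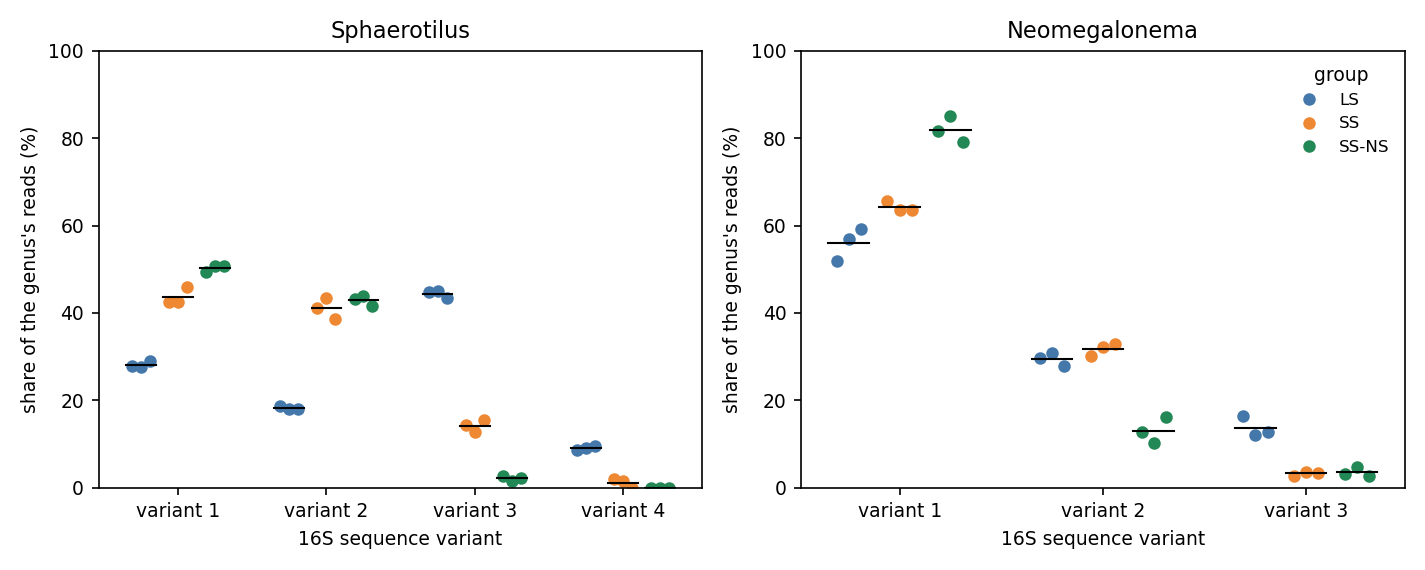
Share of the genus's reads (%, vertical axes) held by the leading 16S sequence variants (horizontal axes) of Sphaerotilus and Neomegalonema, with a point per library, colour for the group and a line at the mean. Sphaerotilus variant 3 averages 44.5% in LS and 2.20% in SS-NS.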

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

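Alternatives chosen after seeing the data were variants outside Sphaerotilus, Sphaerotilus on the PHA-storing list, the most abundant member left out of 4 other lists, totals without Sphaerotilus or without it and Neomegalonema, and the repeated filter in fits with fewer libraries. The others were planned. Leave-one-out fits at first repeated the low-count filter, which dropped genera found in 1 group only, and were then changed to keep the 69 units. Both versions are given.

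In SS against LS, SS-NS against SS, SS-NS against LS and over the 3 groups, counts of called units moved from 48, 41, 50 and 61 to 22, 27, 24 and 29 with a minimum of 50 reads and to 27, 26, 28 and 35 for families, where 31 and 42 units were tested. Single variants gave 69, 67, 78 and 92. With 1 library left out they ranged over 44 to 51, 36 to 41, 50 to 53 and 58 to 62, and with the filter repeated over 28 to 51, 26 to 40, 33 to 50 and 43 to 58. With the filter repeated, SS against LS gave 28, 30 and 29 without LS replicates 1, 2 and 3, SS-NS against SS gave 27 and 26 without SS replicates 1 and 2, and SS-NS against LS gave 33 without LS replicate 1, because fewer genera reach 3 libraries. Other counts stayed within 1.5 times. Without Sphaerotilus in the totals they were 51, 30, 52 and 58, and without Neomegalonema too 51, 31, 48 and 57. Splits into higher and lower moved by scaling in SS against LS to 29 and 22 (DESeq2 size factors) and 31 and 22 (DESeq2), in SS-NS against SS to 27 and 22 (centred log-ratios), and in SS-NS against LS to 23 and 32 (centred log-ratios).

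Pairing by replicate number stays open: same-number correlations of deviations lay between −0.08 and 0.08, and 2 of 9 libraries correlated best with their own number in both other groups. With the replicate block, called units numbered 33, 32, 44 and 49, and the number of variants gave p = 0.0556 by exact permutation over 36 arrangements. Bray-Curtis dissimilarity, the Shannon index and the PHA-storing and filamentous shares, the only lists run with it, gave exact permutation p = 0.0278, the smallest possible there. Among named genera, 8 calls of 90 comparisons were lost under the block: Sphaerotilus, midas_g_11604, Terrimicrobium and Emticicia in SS against LS, midas_g_896, Paracoccus and Azoarcus in SS-NS against SS, and Azoarcus in SS-NS against LS. The cause was not tested.

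The order of SS and SS-NS in the number of variants reversed for genera (exact permutation p = 0.00357), without variants of fewer than 10 reads (p = 0.0107) and outside Sphaerotilus (p = 0.00357). Each p here tests any difference among the 3 groups, not that order. That of the PHA-storing share reversed without Neomegalonema (exact permutation p = 0.00357) and without SS-NS replicate 1. Without its most abundant member the order of the groups changed for flanking Bacteroidota (exact permutation p = 0.0321), predatory (p = 0.786) and anaerobic genera (p = 0.636), and the sewage and gut share gave p = 0.0536. With 1 library left out, exact permutation p was 0.0107 to 0.025 for variants, 0.0179 to 0.0321 for the PHA-storing share and 0.00357 for the Shannon index, the filamentous share and dissimilarity.

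Named genera gave 90 fold changes, leaving out those without reads in either group, whose sign comes from the added count alone. Of 2604 alternative values, 2370 kept the direction and the side of the threshold, 132 lost the call, 46 gained one and 56 changed sign. On centred log-ratios the log2 fold change turned positive in SS-NS against SS for Leadbetterella (3.56), Paracoccus (1.67), Wandonia (1.61), Dyadobacter (1.40), Aurantisolimonas (1.22), Azoarcus (0.78), Flavobacterium (0.35) and Comamonas (0.33), and in SS against LS for Acidovorax (0.07). With DESeq2 size factors and with DESeq2, Acidovorax gave 0.53 and 0.53 in SS against LS, and in SS-NS against SS Leadbetterella gave 0.75 and 0.79, Wandonia 0.32 and 0.32, and Paracoccus 0.23 and 0.22. With library totals, SS against LS gave 0.60 for Acidovorax and 0.01 for Emticicia. With a minimum of 50 reads, Acidovorax gave 0.37 in SS against LS, Neomegalonema −1.17 and Thauera −0.77 in SS-NS against SS, and Sphaerotilus −0.21 and Pseudomonas −0.14 in SS-NS against LS. With Sphaerotilus left out of the totals, Acidovorax gave 0.56 in SS against LS, and Leadbetterella 0.55, Wandonia 0.14 and Paracoccus 0.05 in SS-NS against SS. With Neomegalonema left out too, SS against LS gave 0.87 for Acidovorax, 0.29 for Emticicia and 0.14 for Comamonas, and SS-NS against SS gave 1.31 for Leadbetterella, 0.84 for Wandonia, 0.80 for Paracoccus and 0.38 for Aurantisolimonas. With only the groups compared, Brevundimonas gave −0.03 in SS against LS with either filter and Leadbetterella 0.23 in SS-NS against SS, and with the filter repeated Leadbetterella gave 0.97, Paracoccus 0.06 and Wandonia 0.04. With 1 library left out, values spanned −0.22 to 0.32 for Brevundimonas in SS against LS, −0.27 to 0.49 for Neomegalonema and −1.29 to 0.08 for Leadbetterella in SS-NS against SS, and −0.21 to 1.21 for Pseudomonas in SS-NS against LS. The cause was not tested.

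Fits without 1 library lost a named call 24 times (69 units kept) and 37 (filter repeated). Lost repeatedly were Wandonia and Azoarcus in SS-NS against SS and Sphaerotilus and midas_g_11604 in SS against LS. With the filter repeated, Flavobacterium in SS-NS against LS was lost without LS replicate 1 or 3 (1.20 and 1.29) and Azoarcus there without LS replicate 1 (2.45). The rise of Sphaerotilus in SS-NS against SS held in each fit with the 69 units (edgeR adjusted p 0.000626 to 0.0424), and missed the threshold with the filter repeated without SS replicate 1 (1.29, edgeR adjusted p = 0.0679) or SS replicate 2 (1.42, edgeR adjusted p = 0.0567). It was lost with a minimum of 50 reads (0.23, edgeR adjusted p = 0.283), against adjusted p between 5.86e-15 and 0.000624 under the 4 other scalings in edgeR, DESeq2 or limma. Libraries of 8667 to 11451 reads limit what is seen of rare genera, and 94 of 163 units had too few reads to test.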

Other observations

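The tests of phyla, variant ratios, low-read variants, totals without Sphaerotilus and depth were chosen after the values behind them had been seen, as were the limits that decided them, and the limits for the planned splits of the libraries were written after their counts were seen. Proteobacteria held 64.1% ± 3.02 of reads in LS, 64.5% ± 0.233 in SS and 89.3% ± 3.62 in SS-NS (SD, n = 3, exact permutation p = 0.0357, adjusted p = 0.0357 over 6 phyla). Bacteroidota held 32.8% ± 3.16, 22.4% ± 1.16 and 5.70% ± 3.27, and Verrucomicrobiota 1.53% ± 0.0909, 5.26% ± 0.880 and 0.0528% ± 0.0915 (each exact permutation p = 0.00357, adjusted p = 0.00714). Chloroflexi had 1.0% ± 0.216 of reads in SS and none listed in LS or SS-NS (exact permutation p = 0.0357, the smallest possible when the other groups have no reads, adjusted p = 0.0357). Firmicutes held 0.610% ± 0.339, 5.97% ± 0.462 and 1.91% ± 0.853 (exact permutation p = 0.00357, adjusted p = 0.00714).

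Flavobacterium filum held 0.142% ± 0.0422 of reads in LS, 7.71% ± 0.651 in SS and 0.820% ± 0.688 in SS-NS, while the placeholder species midas_s_8940 held 1.34% ± 0.907 in SS-NS and had no reads listed in LS or SS. Lactobacillus and Ligilactobacillus, lactic acid bacteria, held 0.728% ± 0.442 and 0.282% ± 0.140 in SS, and 0.434% ± 0.592 and 0.682% ± 0.283 in SS-NS. Lactobacillus reads ranged from 6 to 120 between SS-NS libraries. Bacteroides had 0, 38 and 44 reads in the 3 SS-NS libraries. The species were not tested. As genera, Lactobacillus, Ligilactobacillus and Bacteroides passed in none of the 3 comparisons in edgeR as planned. Of the 5 scalings, in SS-NS against LS 4 called Ligilactobacillus and 3 Lactobacillus, in SS against LS 1 and 2, in SS-NS against SS 1 and 0, and none called Bacteroides.

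The ratio of Sphaerotilus variant 3 to variant 1 fell from 1.58 ± 0.0709 in LS to 0.325 ± 0.0215 in SS and 0.0438 ± 0.0106 in SS-NS, 36.1-fold between LS and SS-NS, without overlap between libraries. Variants that are copies within 1 genome would keep 1 ratio if that genome gave all their reads. This argues against 1 genome as the only source of variants 1 and 3. Another strain carrying only 1 of the variants would also change the ratio, so copies within a genome are not excluded. For variants 2 and 1 of Neomegalonema the ratio was 0.529 ± 0.0527 in LS, 0.494 ± 0.0302 in SS and 0.161 ± 0.0431 in SS-NS, 3.29-fold between LS and SS-NS. There LS and SS lay within their spread and only SS-NS departed. For this pair too, 1 genome is argued against only as the source of all reads. The ratio of Sphaerotilus variants 1 and 2 moved less, 1.44-fold, from 1.54 ± 0.0613 in LS to 1.07 ± 0.111 in SS. This exceeded the spread, without overlap (exact permutation p = 0.0107 over the 3 groups). In SS-NS the ratio was 1.17 ± 0.04, near that of SS. Only LS departed, so 1 genome is argued against only as the source of all reads of this pair. A limit of 1.5 times, set earlier but also after the values were seen, would have left this pair open. A candidate explanation, as a hypothesis, is that strains of S. natans replaced each other between the operating modes. These counts cannot decide it, since a different inoculum or time of sampling could give the same ratios, and strain genomes and sequences of the inoculum would be needed.

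SS-NS had more sequence variants than SS but fewer genera. Between 41 and 54 Sphaerotilus variants were listed per SS-NS library, against 3 to 4 in SS and 4 in LS, and outside Sphaerotilus SS exceeded SS-NS by 28.3 variants on average, so the surplus lay in Sphaerotilus. The count outside Sphaerotilus was made without rarefaction and with fewer reads left in SS-NS, so 28.3 partly reflects depth. Of the Sphaerotilus variants with at most 20 reads in an SS-NS library, 78 were listed at that level in 1 library and 10 in each of the 3. Such variants were 3.07 times as frequent per 1000 genus reads (7.68 ± 1.12) as in the next of the genera above 20% of reads (Neomegalonema, 2.50 ± 2.18). This cannot decide on errors at 1 rate per read in every abundant genus. No listed count was below 2, so an error had to recur to be listed, and Sphaerotilus had more reads (mean 5825 against 2369 per SS-NS library). Errors that pass the unnamed denoiser only for a template this abundant could also give the surplus, as could rare strains, and no test here separates them.

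Of the 37 units called lower in SS-NS than in SS, 25 were still called lower with Sphaerotilus left out of the totals and no TMM factors. Of these 25, 18 had no reads listed in SS-NS. This argues against reads taken up by Sphaerotilus as the whole cause for the 25. The other 12, among them Flavobacterium, Aurantisolimonas, Paracoccus and Wandonia, were no longer called. Their median log2 fold change moved from −2.40 (SD between genera 1.96) to −1.09 (SD between genera 2.43), and 10 of the 12 stayed below 0. With library totals alone and Sphaerotilus kept, 8 of the 12 were called, and Paracoccus and Wandonia were not. Part of the loss therefore came with leaving out the TMM factors. For the 12, the explanation cannot be told apart from a true decrease, because the fit changed both and the spread between genera reaches 0. At their SS share, the 21 units without reads would have had at least 13.5 reads in the pooled SS-NS libraries. The lowest were midas_g_896 (13.5), Nannocystis (29.8) and Verrucomicrobium (44.6), which also lacked reads in an SS library, so depth stays open for them. For the others, at 75.0 or more, depth is argued against as the cause. These expectations do not allow for the reads taken up by Sphaerotilus. A true loss of the missing genera from the culture in SS-NS remains a hypothesis.

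Counts of calls were also set against other splits of the libraries. Of 100 of the 280 partitions of the 9 libraries into 3 groups, 1, the real one, gave as many as 61 units, and the highest other gave 26. This argues against a chance assignment of these libraries to the 3 groups. It cannot exclude chance differences between cultures, since the replicates of a group may come from 1 culture. The 10 splits of 6 libraries are too few for a share under 0.05. There the real splits gave 48, 41 and 50 units in SS against LS, SS-NS against SS and SS-NS against LS, and the highest of the other splits gave 0 in each.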
